A study of Nicotiana benthamiana and Pseudomonas syringae pv. syringae and Pseudomonas amygdali pv. tabaci with 27 samples.

How the data were processed

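RNA was sequenced from leaves of Nicotiana benthamiana, a tobacco relative widely used as a host plant in plant pathology, and from 2 bacteria that infect it. The bacteria were Pseudomonas syringae pv. syringae B728a (Psy) and Pseudomonas amygdali pv. tabaci 11528 (Pta). The 27 libraries fell into 9 groups of 3, taken from the sample titles. Plant leaves were sampled before inoculation (0 h) and 5 h after inoculation by syringe, from 3 plants given Psy and 3 given Pta. Bacteria came from the leaf intercellular wash fluid at 5 h (in planta) or from growth on King's B medium (in vitro). Psy in vitro had a pelleted and a not pelleted set. Nothing in the labels said that the replicates of a bacterial group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

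Per the labels' protocols, plant libraries were made with a stranded mRNA kit from KAPA, Psy libraries with RiboMinus depletion of ribosomal RNA and a stranded KAPA kit, and Pta libraries with RiboZero depletion and a TruSeq stranded total RNA kit. The submitters' processing notes name HISAT2 2.2.1, Bowtie2, StringTie 2.2.0, featureCounts and DESeq2, without saying which was used for which organism. The genome builds and the strand setting of the counting were not given in the sources used here. For the plant, the deposited values are whole-number counts per gene, not normalized. For Psy and for Pta, the deposited values are expected counts: 29.3% to 45.3% of genes per library held a count ending in 0.5, and in the Psy in planta libraries 7.29% to 12.5% of genes held a count at another fraction, against 0% in the Psy in vitro libraries (tolerance 0.01). For Psy, counts ending in 0.5 were held by 43.3% to 45.3% of genes in planta and 29.3% to 30.3% in vitro. A read that was split between genes gives such fractions, so overlapping genes and near-identical copies cannot be told apart with certainty. Expected counts were rounded to whole numbers before testing.

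There were 5089 Psy genes under locus tags, 5425 Pta genes with positions on 2 sequences, and 48507 plant genes under identifiers. None of the 3 tables pairs an identifier with a gene name or product, and no genome or annotation was used here. The 2 tests that needed names were therefore not run: those of lists of genes fixed in advance, and that of the difference between strains over shared bacterial genes. A further last entry of the plant table names no gene. It was left out of totals and tests, held 0.0698% to 1.47% of the counts of a library, and was blank for replicate 1 of the 0 h Psy plants. Of the plant genes, 26537 carried an assembly prefix, and all 26537 of these were above 0 in that same library. The remaining 21970 had no prefix, and 0 of them were above 0 there, so the form of a plant identifier follows that library.

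Total counts per library ranged from 5355906 to 13998740 for Psy, from 1462943 to 39663389 for Pta and from 5299656 to 12051898 for the plant. The smallest chi-square statistic per degree of freedom between the counts of 2 libraries of a group was 16.9, over 27 pairs, so no library was a copy of another. Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter at its minimum count of 10, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. The libraries of each organism entered 1 fit with a mean per group. Standard errors were the absolute log2 fold change divided by the square root of F. A group with 0 counts in its 3 libraries was given a floor of 3 counts over the group, and a fold against it is written as "at least"; such floors cover counting error only. Levels are CPM, the share of library counts scaled by TMM, as mean ± SD. The comparisons, tests, rule for named genes and alternatives were fixed before the data were examined, except where stated. By that rule, as identifiers had no names, the identifiers named are the 2 with the largest rise and the 2 with the largest fall past the test. They needed no overlap between the libraries of both groups (not asked of the interaction) and a mean of at least 10 CPM.

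Chosen after the data were seen, because names were lacking, were the analyses of neighbouring genes. A run is an unbroken row of neighbouring genes, on either strand, all past the adjusted p of 0.05 and changed at least 2-fold the same way. Pta genes were ordered by the positions in the deposited table. Psy genes were ordered by locus tag number, taken to follow the genome, and 48 tag numbers absent from the table broke runs. The longest run was compared with 1000 shuffles of the gene order. Shared libraries between both Psy in planta comparisons were simulated 20 times with no true difference.

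Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a minimum change of 2-fold, fits of only the groups compared, each library left out in turn, and a replicate block. The series text says that the same plants were sampled at both times, and the replicate number was taken to mark the plant within a strain. Deviations of same-numbered plant libraries from their group means correlated at 0.02 to 0.08 for Psy plants and 0.07 to 0.11 for Pta plants. The rRNA and tRNA genes could not be left out, as the tables do not mark them. Added after the data were seen were thinning of the Pta in planta libraries to the mean in vitro depth and fits without plant genes listed at 0 in 1 group and at 10 or more counts in every library of the others.

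The procedure was tested on simulated counts with the depths and spread of the real libraries and 1 mean per gene over all libraries of an organism. The 200 genes changed were drawn only from genes above a minimum expected count, so recovery of weakly expressed genes was not measured. Of genes changed by a log2 fold of 1, 2 and 3, it recovered 13.4%, 86.6% and 97.0% for Psy in planta against pelleted, and 67.2%, 100% and 100% for Pta. False calls were 5.76% and 5.32% of all calls in these simulations. For the plant response to Psy it recovered 0%, 1.49% and 35.9%. For the difference between both plant responses it recovered 0% at each of these sizes. With only 200 changed genes, of 24716 tested for the response to Psy, the Benjamini-Hochberg cutoff is stricter than where many genes change. The real response to Psy had 5900 calls, so recovery there may be higher than in this simulation. The same applies to Psy in planta against pelleted and to Pta, with 3045 and 3590 real calls. The other plant comparisons were not simulated.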

Results

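The transcriptomes of N. benthamiana leaves and of the 2 Pseudomonas strains were measured by RNA sequencing, with 3 libraries in each of 9 groups. Psy libraries held 8748359 to 13998740 counts in planta, 5355906 to 11726254 pelleted and 11391563 to 12586032 not pelleted. Pta libraries held 9654792 to 39663389 counts in planta and 1462943 to 5679886 in vitro. Plant libraries held 8740632 to 9159907 counts at 0 h and 5299656 to 7462293 at 5 h in Psy plants. In Pta plants they held 9525366 to 11774797 at 0 h and 7702260 to 12051898 at 5 h. Along the first principal component, bacteria in planta lay apart from those in vitro and plants at 5 h apart from plants at 0 h. Pelleted and not pelleted Psy overlapped on it, as did Psy and Pta plants at 0 h. Replicate 1 of the pelleted Psy set and replicate 2 of the 5 h Psy plants lay apart from their groups along the second component, at -65.4 and 221. So did Pta in vitro replicate 3, at 29.9 against -17.5 and -18 for replicates 1 and 2. Replicate 2 of the 5 h Psy plants was also apart on the first component, at 246.5 against 112.4 and 165.9. Its 10 most abundant genes held 26.0% of counts, against 9.20% and 10.1% in replicates 1 and 3.

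**Figure D1:**
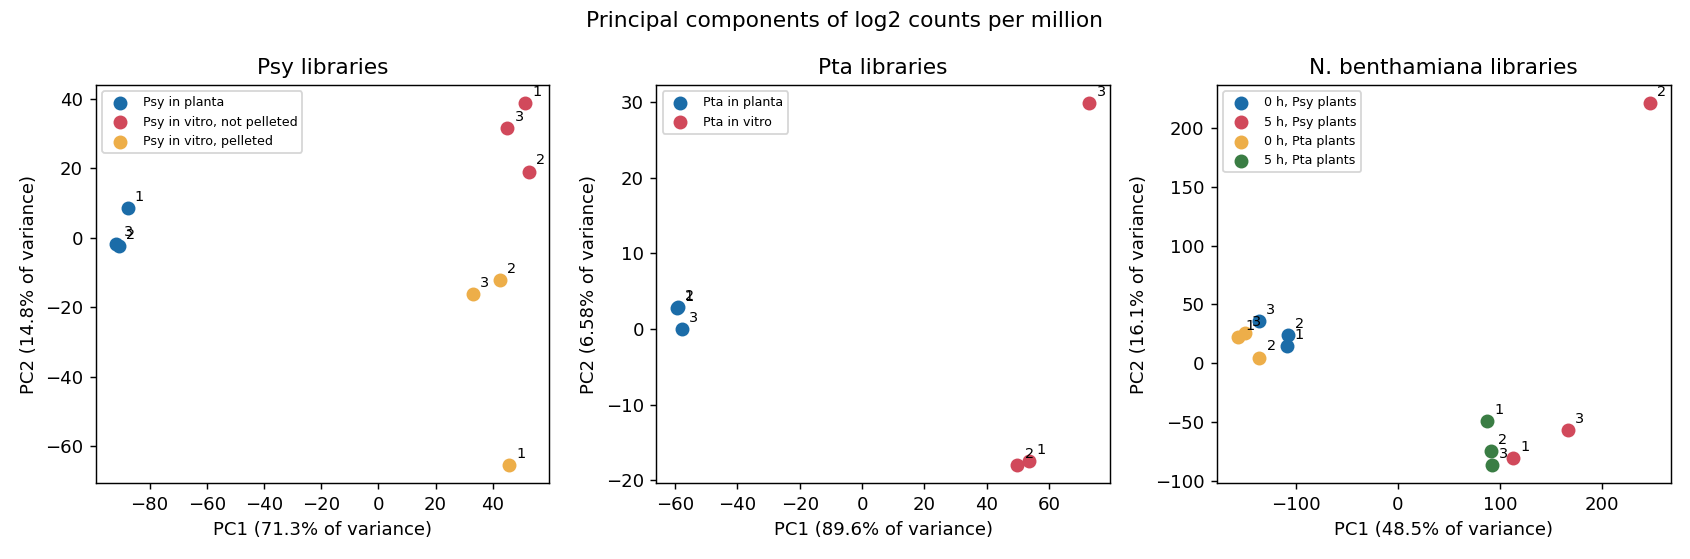
Principal components of log2 CPM for the Psy, Pta and plant libraries, 1 point per library, coloured by group and numbered by replicate; axes give the share of variance. Bacteria in planta and in vitro, and plants at 0 h and 5 h, lie at opposite ends of the first component, which holds 71.3%, 89.6% and 48.5% of the variance.

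The first question was how Psy in the leaf differed from Psy grown on medium. In planta, 1434 genes were higher and 1611 lower than in the pelleted culture, of 5085 tested. Psyr_0750 rose most, from 7.28 ± 1.5 to 4492 ± 1790 CPM (SD, n = 3 per group), 617-fold. Psyr_4316 followed, from 1.10 ± 1.4 to 234 ± 129 CPM. Psyr_2047 fell from 2649 ± 3760 to 2.06 ± 0.42 CPM and Psyr_2046 from 709 ± 1130 to 0.618 ± 0.088 CPM. The pelleted level of both rested on uneven libraries: Psyr_2047 stood at 6.34, 6960 and 985 CPM in replicates 1, 2 and 3. The log2 fold changes in edgeR's quasi-likelihood test were 9.26 ± 0.52 (SE, adjusted p = 4.59e-06), 7.68 ± 0.95 (0.000101), -10.32 ± 2.10 (0.00199) and -10.13 ± 2.27 (0.00346). Without pelleted replicate 2 they were -7.90 for Psyr_2047, -6.54 for Psyr_2046 and 9.07 for Psyr_4316. With the replicate number as a block, Psyr_2047 was at -9.03 and Psyr_2046 at -8.31.

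Large falls outnumbered large rises. At least 4-fold changes were 489 rises and 738 falls, and at least 16-fold changes 45 rises and 224 falls. Neighbouring genes moved together. The longest run of rises covered 39 genes, locus tags 4523 to 4561, with log2 fold changes of 1.99 to 5.30 (mean 3.11). These 39 genes held 16.3 ± 0.41% of all Psy counts in planta, 1.44 ± 0.81% in the pelleted culture and 1.03 ± 0.15% in the culture that was not pelleted (SD, n = 3 each). A second run, the 18 tags from 5120 to 5137 at the end of the numbering, rose by a mean of 2.47 and went from 0.197 ± 0.11% to 1.89 ± 0.20% of counts. The longest run of falls covered 23 genes, tags 3427 to 3449, with a mean of -4.25. A further 16 neighbouring genes, tags 3451 to 3466, had a mean of -4.77 and went from 12.1 ± 0.80% of counts in the pelleted culture to 0.516 ± 0.076% in planta. Shuffled gene orders gave no run over 11 rising or 12 falling genes (permutation p = 0.001 for each, the smallest that 1000 shuffles can give), and genes are not independent of each other. With 3 libraries against 3, a single share can reach an exact permutation p no lower than 0.1, so the shares were not tested.

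Against the culture that was not pelleted, 1551 genes were higher in planta and 1636 lower. In that comparison, 36 of the 39 genes of the long rising run were at least 2-fold higher past the test, as were 17 of the 18 at tags 5120 to 5137. All 23 genes at tags 3427 to 3449 and all 16 at tags 3451 to 3466 were lower. Of the other long runs against the pelleted culture, 9 of 13 genes at tags 4590 to 4602 were higher and 14 of 22 at tags 2551 to 2572 lower. Of these 13 genes, 7 were lower and 0 higher in the pelleted than in the not pelleted culture. They held 0.173 ± 0.016% of counts in planta, 0.0191 ± 0.0067% pelleted and 0.0797 ± 0.050% not pelleted. The pelleted share of the 22 genes was uneven, at 0.0809%, 0.0197% and 0.0206% in replicates 1, 2 and 3. Both references gave 1099 genes higher and 1230 lower in planta, and 27 genes opposite calls. Independent lists of these sizes would share 437 and 518 genes. Both comparisons use the same in planta libraries, and part of the excess may come from that. Simulated libraries with no difference shared 0 calls. Where no gene truly differs few are called at all, so this 0 cannot measure that part. The simulated fold changes of both comparisons had a mean covariance of 0.08 against 3.46 observed, and a mean Pearson correlation of 0.49 against 0.89. These values show only what noise in the shared libraries gives without true changes.

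**Figure D2:**
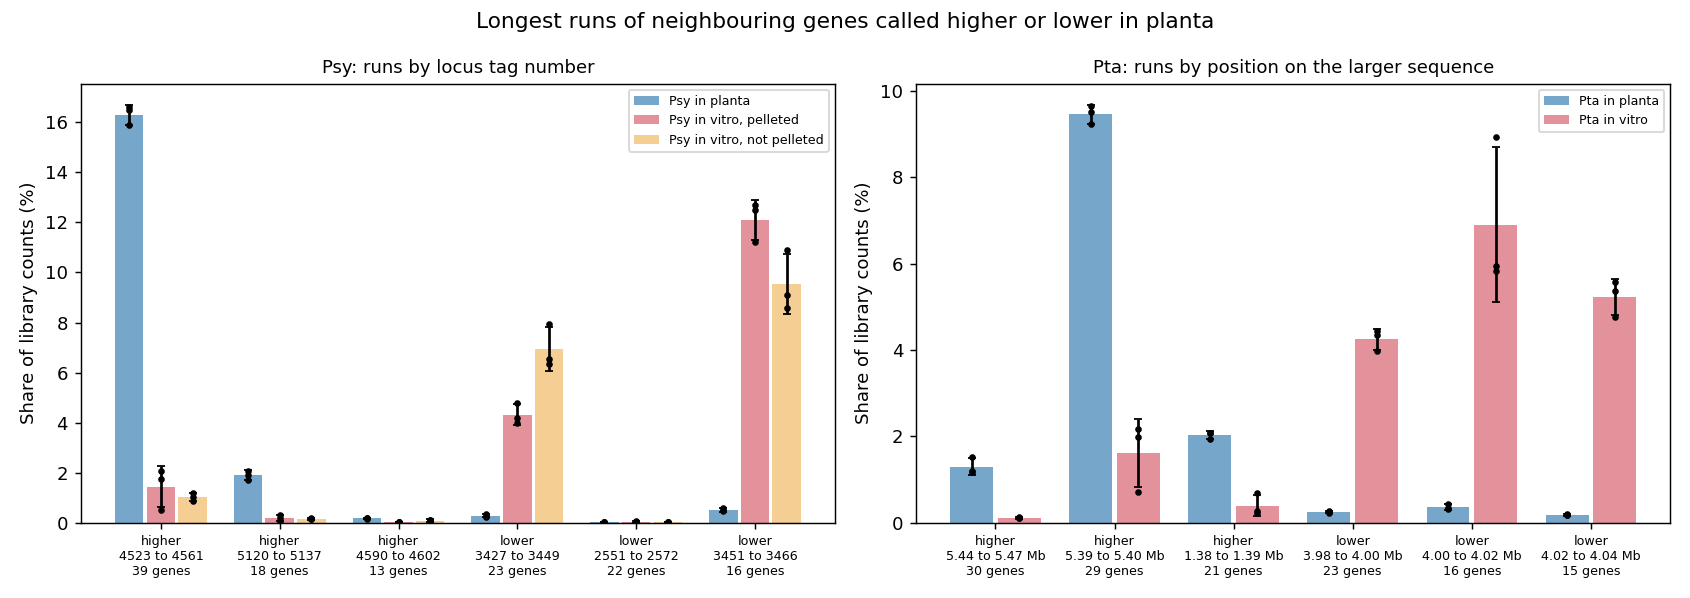
Share of library counts held by the 3 longest runs of rising and of falling neighbouring genes in Psy (in planta against pelleted) and Pta (in planta against in vitro); bars are means, error bars SD, and points the 3 libraries of a group. The 39 Psy genes at tags 4523 to 4561 held 16.3% of counts in planta and 1.44% in the pelleted culture, and 29 Pta genes near 5.39 Mb held 9.47% and 1.62%.

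The second question was whether pelleting itself changed the Psy transcriptome. Pelleted and not pelleted cultures differed in 1353 genes, 689 higher and 664 lower after pelleting, and 1 gene changed at least 16-fold. Psyr_3884 went from 2142 ± 955 to 120 ± 37 CPM with pelleting (SD, n = 3 per group), a log2 fold change of -4.16 ± 0.44 (edgeR adjusted p = 0.0041), and Psyr_0070 from 601 ± 187 to 58.4 ± 42 CPM (-3.36 ± 0.66, adjusted p = 0.00913). Psyr_5098 rose from 171 ± 135 to 2409 ± 2290 CPM (3.82 ± 0.98, adjusted p = 0.0212) and Psyr_1972 from 14.5 ± 13 to 196 ± 153 CPM (3.76 ± 0.83, adjusted p = 0.0124). The longest runs held 5 genes in either direction, against at most 8 rising and 6 falling genes over 1000 shuffled orders (permutation p = 0.08 for rises and 0.02 for falls). Neither run held under all alternatives. Without not pelleted replicate 3, 1 gene of the rising run was still called at 2-fold. With only the compared libraries in the fit, 3 genes of the falling run were.

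The count for pelleting depended on the libraries and the test. It was 619 when the in planta libraries did not enter the fit, 2037 with DESeq2, 583 without not pelleted replicate 1 and 488 without not pelleted replicate 3. Psyr_5098 did not pass the test without either of these 2 libraries (3.31 and 3.91) or with the replicate number as a block (4.13), nor did Psyr_1972 without not pelleted replicate 3 (3.67). Without pelleted replicate 1, their log2 fold changes were 2.69 and 2.94, and without not pelleted replicate 2 they were 4.46 and 4.64.

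The same question was asked of Pta in the leaf. In planta, 1787 genes were higher and 1803 lower than in vitro, of 5416 tested. PSYTB_RS03895 rose from 29.5 ± 14 to 9168 ± 1590 CPM (SD, n = 3 per group), 311-fold, and PSYTB_RS08150 from 29.7 ± 8.9 to 9153 ± 1570 CPM, 308-fold. Their counts were nearly alike in planta (414569 and 411370 in replicate 1) and less so in vitro (112 and 94 in replicate 1, 186 and 200 in replicate 2, 18 and 24 in replicate 3). Reads may have been split between near-identical copies, so the level of each is uncertain. PSYTB_RS20475 fell from 803 ± 600 to 6.24 ± 1.6 CPM and PSYTB_RS23595 from 5074 ± 2330 to 43.5 ± 7.1 CPM. The log2 fold changes were 8.24 ± 0.48 (edgeR adjusted p = 3.6e-06), 8.23 ± 0.40 (2.06e-06), -6.99 ± 0.63 (2.89e-05) and -6.87 ± 0.44 (4.92e-06), and without in vitro replicate 3 that of PSYTB_RS20475 was -6.20.

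At least 2-fold changes were 1078 rises and 1138 falls, and at least 16-fold changes 49 rises and 161 falls. The longest run of rises held 30 genes between positions 5442303 and 5467538 of the larger sequence, with a mean log2 fold change of 3.56. It went from 0.108 ± 0.014% to 1.30 ± 0.19% of counts (SD, n = 3). A second run of 29 genes, all on the same strand from 5387610 to 5402934, rose by a mean of 2.31 and from 1.62 ± 0.79% to 9.47 ± 0.22% of counts. The 3 longest runs of falls lay one after another between 3975946 and 4037467, with 23, 16 and 15 genes and means of -4.13, -3.99 and -4.96. They held 4.25 ± 0.25%, 6.91 ± 1.8% and 5.23 ± 0.42% of counts in vitro, against 0.255 ± 0.023%, 0.365 ± 0.060% and 0.178 ± 0.017% in planta. Shuffled orders gave no run over 9 genes in either direction (permutation p = 0.001, the smallest that 1000 shuffles can give).

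On the smaller Pta sequence, whose last gene ends at position 67597, 13 of 71 genes changed at least 2-fold, or 18.3%. On the larger sequence 2203 of 5345 did, or 41.2% (Fisher's exact test, two-sided p = 7.56e-05; this comparison was chosen after the data were seen, and genes are not independent).

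In the plant, the question was how leaves changed by 5 h after inoculation. In Psy plants 2631 genes were higher and 3269 lower at 5 h than at 0 h, of 25571 tested. As groups picked by the test itself, the genes called higher went from 2.88 ± 0.14% to 27.2 ± 7.6% of all plant counts, and genes called lower from 57.7 ± 2.2% to 10.7 ± 4.5% (SD, n = 3). NbD027074 and NbD048241 were at 0 in all 0 h libraries and reached 262 ± 197 and 178 ± 209 CPM. If 0 is a true count, they were at least 1760-fold and 1190-fold higher. NbD048267 and NbD021918 stood at 613 ± 103 and 150 ± 75 CPM at 0 h and at 0 in all 5 h libraries, at least 4230-fold and 1030-fold lower if 0 is a true count. That is in doubt in this group, where of genes with 10 or more counts in every other plant library 61 were listed at 0 and 3 had a sum of 1 to 3. The edgeR adjusted p of these 4 genes were 0.00112, 0.00779, 0.00701 and 0.000102. At least 16-fold calls were 594 rises and 879 falls. Without 5 h replicate 2 the fitted log2 fold changes went from 14.23 to 13.51 for NbD027074 and from 13.67 to 12.13 for NbD048241, which are no bounds. The count was 3206 when only the libraries of Psy plants entered the fit, 3724 without 0 h replicate 3 and 8004 with DESeq2. With the plant as a block it was 4003, with 1614 higher and 2389 lower.

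In Pta plants 2629 genes were higher and 2373 lower at 5 h. This balance turned with the scaling, to 2288 higher and 2665 lower with RLE and 3195 higher and 3792 lower with DESeq2. Genes called higher went from 3.15 ± 0.57% to 26.3 ± 0.33% of plant counts, and genes called lower from 55.0 ± 4.4% to 14.3 ± 2.6% (SD, n = 3). NbD005168 and NbD042478 went from 0 in all 0 h libraries to 869 ± 709 and 567 ± 222 CPM, at least 8350-fold and 5450-fold higher if 0 is a true count. In the Pta 0 h group too, of genes with 10 or more counts in every other plant library, 14 were listed at 0 and 0 had a sum of 1 to 3. NbD021427 and NbD012204 went from 102 ± 10 and 78.4 ± 28 CPM to 0, at least 1370-fold and 1050-fold lower if 0 is a true count. The edgeR adjusted p of these 4 genes were 0.00101, 0.000558, 0.00319 and 0.000323. Without 5 h replicate 3 the fitted log2 fold change of NbD005168 went from 15.96 to 15.04. With the plant as a block the count was 3325, and without 0 h replicate 1 or 3 it was 2833 or 2921. When only the libraries of Pta plants entered the fit it was 7138, against 3206 for Psy plants fitted the same way. Which response had more calls thus turned with the fit, as the main counts were 5002 for Pta and 5900 for Psy.

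The changes from 0 h to 5 h, called responses here, ran in parallel in both sets of plants. They shared 1683 genes called higher and 1947 called lower, where independent lists would share 270 and 303. Opposite directions were called for 5 genes. The samples held no leaves at 5 h without bacteria. Shared changes therefore cannot be told apart from effects of the syringe or of time. Of the genes called in Psy plants, 98.3% had the same sign in Pta plants, and of those called in Pta plants 98.1% had the same sign in Psy plants. Across all 25571 genes, which are not independent replicates, the log2 fold changes correlated at Pearson 0.76 and Spearman 0.79. With RLE in place of TMM scaling, the median log2 fold change of all genes moved from 0.05 to -0.06 in Pta plants and from -0.12 to -0.08 in Psy plants.

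**Figure D3:**
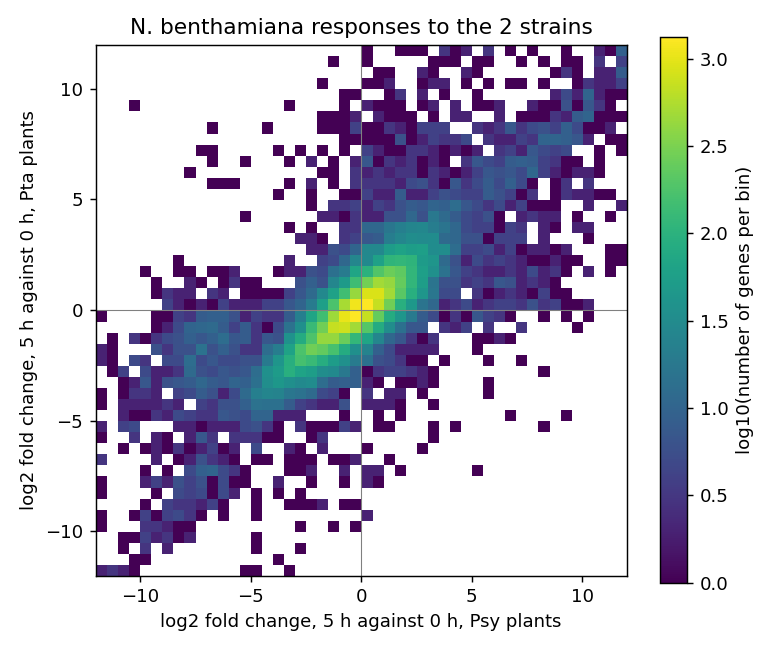
Log2 fold change at 5 h against 0 h in Psy plants (x axis) and Pta plants (y axis) for 25571 genes, in bins of 0.5, coloured by the log10 number of genes per bin; values beyond 12 are drawn in the outermost bin. Genes lie along the diagonal, with a Pearson correlation of 0.76 across genes.

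Whether the responses differed was tested as an interaction. It called 48 genes, 6 with a higher and 42 with a lower log2 fold change in Psy plants. NbD032800 stood at 53.3 ± 8.9 CPM at 0 h and 0 at 5 h in Psy plants, and at 74.5 ± 44 and 70.6 ± 45 CPM in Pta plants (SD, n = 3 each). NbD019069 went from 18.3 ± 6.9 to 239 ± 131 CPM in Psy plants, and from 0, as listed in the group with 14 such zeros, to 427 ± 242 CPM in Pta plants. NbD037703 and NbD048224 were at 0 at 0 h in Psy plants and reached 115 ± 76 and 73.5 ± 32 CPM, while in Pta plants they rose 4.86-fold and 5.96-fold. NbD037703 and NbD048224 are the 2 genes listed at 0 in the Psy 0 h group and at 10 or more counts in every other plant library. Already at 0 h, NbD037703, NbD048224 and NbD019069 differed between the Psy and Pta plants past the test, and all 3 rose in both sets by 5 h. Each of these 0 h differences rests on a group listed at 0 and is in doubt if 0 is not a true count. Of the 48 genes, 8 were called at 0 h between these plants and 40 at 5 h. The edgeR adjusted p were 0.0255, 0.0196, 0.0196 and 0.0086, and none of the 4 passed the test with the plant as a block, where the log2 differences were about as large (-11.75, -11.25, 10.85 and 9.90).

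As listed in the table, 40 of the 48 genes were at 0 in all libraries of 1 group and at 10 or more counts in every other plant library, 34 of them in Psy plants at 5 h. Without the 79 genes of this kind, a choice made after the data were seen that removes 40 of the 48 by construction, edgeR called 0 genes (1409 at an unadjusted p under 0.05) and DESeq2 169, of which 7 were among the 48. With the plant as a block edgeR also called 0 (1206 unadjusted), and DESeq2 without these choices called 281. The edgeR count was 288 without Psy 5 h replicate 1, 77 without Psy 5 h replicate 2, 31 without Psy 0 h replicate 1, and 17, 13 and 18 without Pta 0 h replicates 1, 2 and 3. It was 28 without Pta 5 h replicate 1 and 28 without replicate 2.

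Before inoculation, the Psy and Pta plants differed in 29 genes, 25 higher and 4 lower in Psy plants, and at 5 h in 141, 41 higher and 100 lower. Without genes listed at 0 in 1 group only, these counts were 19 and 31. At 5 h this left 22 higher and 9 lower, a turn that the choice makes only in part: 61 of the 79 genes left out are at 0 in Psy plants at 5 h, and the other lost calls no longer passed the test. With only the libraries compared in the fit, edgeR called 131 genes at 0 h and 0 at 5 h (1387 at an unadjusted p under 0.05). DESeq2 called 474 and 878, and the replicate number as a block left 4 at 0 h. At 0 h, leaving out 1 library gave 0 to 43 genes, with 0 without Pta replicate 3, 1 without Pta replicate 2, 3 without Pta replicate 1, 2 without Psy replicate 1 and 14 without Psy replicate 2. At 5 h it gave 626 without Psy replicate 1 and 80 without Pta replicate 2.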

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

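Chosen only after the result was seen were the count of genes at 0 against low counts, the refits without genes listed at 0, and the permutation test of the entry that names no gene. The splits of the libraries were planned.

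The difference between the plant responses to Psy and Pta was tested as an interaction and called 48 genes, as well as each of NbD037703 (log2 difference 10.76 ± 1.30, SE), NbD048224 (9.82 ± 0.95), NbD032800 (-11.85 ± 1.53) and NbD019069 (-11.22 ± 1.34). These fitted values rest on groups at 0 and are no bounds. None of the 4 passed the test with the plant as a block, at 10.85, 9.90, -11.75 and -11.25. Without Pta 0 h replicate 1, 2 or 3, or Pta 5 h replicate 1, NbD037703 (10.47 to 10.76), NbD019069 (-11.25 to -11.21) and NbD032800 (-12.31 to -11.40) did not pass. NbD032800 also did not pass without Psy 0 h replicate 1 (-11.82), 2 (-12.02) or 3 (-11.81) or Pta 5 h replicate 2 (-11.55). Without each library in turn, the calls ranged from 13 to 288: 288 without Psy 5 h replicate 1, 77 without Psy 5 h replicate 2, 31 without Psy 0 h replicate 1, 17, 13 and 18 without Pta 0 h replicates 1, 2 and 3, and 28 without Pta 5 h replicate 1 or 2.

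Of the 48 calls, 34 belonged to 61 plant genes at 0 in all 3 Psy 5 h libraries and at 10 or more counts in each of the other 9, among them NbD032800 but not the other 3 genes named. Low depth of the Psy 5 h group was tested on 17641 genes with 10 or more counts in every 0 h library. Of these, 305 were at 0 in all Psy 5 h libraries and 83 in all Pta 5 h libraries. Thinning the latter to the Psy 5 h depths left 83, closing 0% of the gap. This argues against low depth acting only as sparser sampling of the listed counts. Thinning finished counts cannot repeat a counting step that lists weakly covered genes at 0, so depth acting through such a step stays open. Of the 61 genes, 0 became 0 in all 3 thinned libraries, which their choice by counts in Pta plants already fixed. A candidate explanation is a step of gene counting or table making that lists a gene at 0, as 61 genes had a sum of 0 and 55 a sum of 1 to 10. Whether their reads entered the entry that names no gene stays open: in 3 of 3 Psy 5 h libraries it held far more than the counts missing, but it was as large in the Pta 5 h libraries (0.546% to 1.44%), where 2 genes were so listed. Loss of these transcripts after Psy inoculation also stays open, as the same genes had a median log2 fold change of -1.64 in Pta plants and no test here separates loss from listing at 0.

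More genes at 0 than at low sums were also found in the Pta 0 h group, with 14 at 0 and 5 at a sum of 1 to 10 among genes with 10 or more counts in every other library. These 14 include 3 of the 48 calls, among them NbD019069. In the Psy 0 h group 2 such genes were at 0, NbD037703 and NbD048224, and 11 at a sum of 1 to 10. More zeros than low counts also appeared in single libraries. Among genes with 10 or more counts in the other 11 plant libraries, replicate 2 of the 5 h Psy plants had 1531 at 0 and 112 at 1 to 3 counts, and the other 11 libraries had 4 to 91 at 0 and 0 to 6 at 1 to 3 counts.

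The plant entry that names no gene is outside all comparisons and held more counts after inoculation. It made up 0.985 ± 0.43% of counts at 5 h (SD, n = 6) and 0.216 ± 0.12% at 0 h (SD, n = 5, since 1 library is blank), with each 5 h library, at 0.530% or more, above each 0 h library, at 0.354% or less (exact permutation test over 462 splits, two-sided p = 0.0065, treating libraries of 1 plant as separate).

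With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave the most calls in each comparison, 1 of 10. Every other split puts libraries of both conditions into each group, so a real difference widens the spread within groups. Low counts in the other splits follow in part from that and are no measure of chance. The real and the highest other counts were 3045 and 0 for Psy in planta against pelleted, 3187 and 0 against not pelleted, 1353 and 3 for pelleting, and 3590 and 0 for Pta. They were 5900 and 14 for the plant response to Psy, 5002 and 1 for Pta, 29 and 6 between plants at 0 h, and 141 and 16 at 5 h. For the interaction, splitting the 6 plants gave 48 and 13. Among the 3 other splits that also part all 3 same-numbered pairs of a response, the highest counts were 14 for Psy and 0 for Pta (edgeR).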

How the results depend on the processing

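Chosen after the data were seen were the thinning of the Pta in planta libraries and the fits without genes listed at 0. Of 119 counts of calls under an alternative, 83 stayed within 1.5 times the reported count, and of 313 values of named genes 289 kept direction and call, 24 no longer passed the test and 0 reversed. For Psy in planta the calls were 2534 to 3374 against pelleted and 2661 to 3736 against not pelleted, leave-one-out fits included. For Pta they were 2216 with a 2-fold minimum, which removes smaller changes by construction, and otherwise 3083 to 3741, with 3414 after thinning to the mean in vitro depth. In the other comparisons the cause was not tested, except that fits with fewer libraries or genes hold less data.

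Leaving out single libraries gave 488 to 1898 calls for pelleting, 3724 to 6678 and 2833 to 3672 for the plant responses to Psy and Pta, 13 to 288 for the interaction, 0 to 43 (0 with 1369 at an unadjusted p under 0.05) between plants at 0 h and 80 to 626 at 5 h. DESeq2 gave 2037 for pelleting, 281 for the interaction, 474 at 0 h and 878 at 5 h. With only the libraries compared, edgeR gave 619 for pelleting, 3206 for the response to Psy and 7138 for that to Pta. Between plants it gave 131 at 0 h and 0 at 5 h. Without genes listed at 0, edgeR gave 0 for the interaction, 19 at 0 h and 31 at 5 h, and DESeq2 169 for the interaction. DESeq2 moved the share of higher calls from 12.5% to 31.3% in the interaction and from 29.1% to 44.9% at 5 h. RLE scaling moved the median log2 fold change of the interaction from -0.22 to -0.06.

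With the plant as a replicate block, the calls were 3325 for the response to Pta, 0 for the interaction and 4003 for the response to Psy. With the replicate number as a block they were 4 between plants at 0 h, 96 at 5 h, 932 for pelleting, 2849 and 3031 for Psy in planta against pelleted and not pelleted, and 3281 for Pta. Bacterial samples share only a number: deviations of same-numbered libraries correlated at -0.18 to -0.12 (Psy in planta and pelleted), 0 to 0.31 (in planta and not pelleted), -0.10 to 0.16 (both cultures) and -0.08 to 0 (Pta). Gene lists, the strain difference over shared genes and the fits without rRNA and tRNA genes were not run, for lack of gene names. The shallowest library, Pta in vitro replicate 3, held 1462943 counts, and without it Pta had 3741 calls.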

Other observations

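Chosen only after the result was seen were the tests of neighbouring Pta genes and of the pelleted library that stands apart. The thinning of the in vitro libraries and the tests of fractional counts and of abundant genes were set before their results were seen.

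Pta genes close together on a strand had similar fold changes. For 1000 pairs of neighbours on the same strand with a gap under 50 bp, the log2 fold changes in planta against in vitro correlated at Spearman 0.89 across pairs, with a median absolute difference of 0.35. The correlation was 0.58 over 1274 pairs with a gap of at least 50 and under 200 bp, 0.30 over 597 pairs with a gap of 200 bp or more, and 0.35 over 1572 pairs on opposite strands. Coding length was nearly unrelated to the fold change (Spearman 0.0023). The difference of 0.54 between close neighbours and those on opposite strands is consistent with transcription of neighbours as units, a hypothesis found on these data. Pairs on opposite strands were not matched by gap, so this difference mixes strand with distance. Overlapping neighbours on the same strand, 920 pairs in which reads may be split between genes, correlated at 0.88. Pairs are not independent, and reads that span a short gap could add to the difference.

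Some plant genes went from 0 to 10 or more counts, or the reverse, in every library. In Psy plants 199 genes were at 0 in all 0 h libraries and at 10 or more in all 5 h libraries, and 348 the reverse. In Pta plants these were 364 and 161.

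The difference between pelleted and not pelleted Psy was weighed against 2 technical explanations. Pelleted replicate 1 stands apart, but without it the calls were 1898, against 1353 with all libraries. Lower depth of the pelleted set is argued against too, since thinning all 6 in vitro libraries to the shallowest gave 1279 calls. An effect of pelleting may thus be present, as a hypothesis, but culture or handling differences between both sets cannot be excluded by the labels, and the 488 calls without not pelleted replicate 3 show how far the count leans on single libraries.

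Among Psy libraries, only those in planta held counts at fractions other than 0.5, so counting or sequencing may have differed from that of the cultures. That genes were called because they held fractions other than 0.5 is argued against. At matched mean count, 64.6% of genes without such a fraction were called against 61.5% of genes with one. A difference in counting across all genes of the in planta libraries would not show in this test. Counts ending in 0.5 were also more frequent in planta, in 43.3% to 45.3% of genes per library against 29.3% to 30.3% in the cultures. Their part in the calls was not tested. A few abundant genes as the whole cause are argued against too: under scaling by total counts alone, leaving out the 33 genes among the 10 most abundant of any Psy library moved the median log2 fold change by -0.23, and 2886 of 3161 other calls stayed. With TMM scaling, 3008 of 3013 stayed, which decides nothing because the median did not move. A difference in sequencing or library batch between in planta and in vitro Psy is confounded with the groups and stays open.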
